A study of Homo sapiens with 12 samples.

How the data were processed

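RPE1, an immortalised human retinal pigment epithelial cell line, was transfected for 24 h with siRNA against Anillin or with a non-targeting siRNA using Lipofectamine RNAiMAX, per the labels' protocols. Anillin (ANLN) is a scaffold protein of the contractile ring, and the series title names its knockdown as a way to make polyploid cells through failed cytokinesis. Living cells were stained with Hoechst 33342 at 2 µg/mL for 60 min at 37 °C and sorted by DNA content into 2N and 4N fractions, per the labels' protocols. This gave 4 groups of 3 RNA-seq libraries, 12 in all, which are called control 2N, control 4N, Anillin 2N and Anillin 4N. The labels call the 3 libraries of a group biological replicates without saying whether they came from separate cultures, so the p-values measure only the spread between these samples. The sample numbers in the labels do not tie a 2N fraction to a 4N fraction, and replicates were numbered within each group in the order of deposit.

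The authors deposited a single table of RPKM values, with 57773 gene identifiers and 1 column per library. CASAVA 1.8.2, TopHat2, edgeR and the build hg19 are named without a role in the submitters' processing notes. The annotation, the counting tool and whether counting used strand are not given in the sources used here. Per the labels' protocols the libraries were made with a stranded mRNA kit, while another label field describes ribo-depleted total RNA, and the labels do not settle which selection was used. Gene names came from a gene name table or from GENCODE 29 for all but 5435 identifiers. Coordinates are those of GENCODE 29 on GRCh38, a later build than the one the submitters name.

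For most genes above 0, the deposited RPKM was a whole number of reads divided by the library total and by the genomic span of the gene, introns included. With spans from GENCODE 29, the 12 values of 29238 genes were whole multiples of 1 read, within a tolerance of 0.01 read, and for another 9333 genes the step came from the common divisor of their own values. All 38571 genes above 0 gave whole reads in this way, though for genes above 0 in few libraries a common divisor is bound to be found. Of common-divisor genes above 0 in all 12 libraries, 100% had an implied length of a whole number of bases. The recovered reads summed to between 17412742 and 61760450 per library, and the authors' further scaling between libraries lay between 0.951 and 1.04. RPKM by genomic span places long genes low, so a fixed filter and pseudocount weigh most on them: of genes with enough recovered reads to be tested, 70.9% with a span up to 10 kb, 58.5% of 10 to 50 kb and 29.8% over 50 kb passed the filter on RPKM. Values are relative to the reads of a library, so RNA per cell was not measured.

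Genes with an RPKM of at least 0.5 in at least 3 of the 12 libraries (12892 genes) were tested with limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 0.5). The fit had 1 mean per group over all 12 libraries, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 changes are on this scale, which understates the change of genes with low values. They are given ± SE, and group levels as mean RPKM ± SD over 3 libraries. Tables and figures were made with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Because of the span in the values, limma-voom on the recovered reads (genes with at least 10 reads in at least 3 libraries, 22404 genes) was added after the data had been seen, and so were log2 RPM.

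Groups, comparisons, tests, gene lists, the rule for named genes and the other settings were chosen before the data were examined, apart from those said to have been added later. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list and with fry. A list needed at least 5 measured members. The 20 lists were G1/S and DNA replication, G2/M and mitosis, p53 targets, YAP/TAZ-TEAD targets, G1 cyclins and CDK inhibitors, cytokinesis and septins, interferon-stimulated genes, inflammatory and secretory genes, cholesterol synthesis, TGF-beta response and extracellular matrix, ATF4 and unfolded protein response, immediate early genes, heat shock, centrosome and centriole, mitochondrially encoded messenger RNAs, housekeeping genes, replication-dependent histones, and markers of retinal pigment epithelium, of blood cells and of other epithelia and muscle. The last 3 had 4, 1 and 0 members past the filter and were not tested in the fit on RPKM. Their most abundant members were KRT18 at a mean RPKM of 109.1, CD68 at 15.1 and KRT19 at 0.0616.

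Per comparison of a pair of groups, the rule named the 6 largest rises and 6 largest falls among genes past the threshold whose libraries did not overlap between the groups, with a mean RPKM of at least 2 in 1 group. For the interaction the 6 largest in each direction were taken without the condition on overlap. From each list it took up to 2 members with the largest rise and up to 2 with the largest fall. ANLN, CDKN1A, MDM2, CCND1, CCND2, CCNE1, CCNE2, CCNB1, MKI67, LATS2, CCN2, CCN1, PLK4, ACTB and GAPDH were named whatever their result, and gene symbols of small RNAs were passed over among the largest changes. Short features without a symbol escaped this and took places among the largest changes. CCND2, CCNE1 and LATS2 did not pass the filter on RPKM. Where 5 or fewer members of a list past its test moved in a direction, all of them are named, and those beyond the rule were chosen after their values were seen. Some genes that these conditions name are not reported here, and counts of named genes and of list members include them. Reads of near-identical copies cannot be assigned with certainty, which concerns histones, C4A and C4B, and the pseudogenes HMGN2P32, RPS27P2 and HIST2H3PS2; genes overlapping on the other strand are uncertain too.

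The test was run on simulated libraries with known changes, drawn from the gene means over all libraries and the real library sizes. All genes had 1 spread (squared coefficient of variation 0.0021, a median over well-counted genes). They varied independently and few were changed, so recovery and false calls in the real data can differ. Of genes changed 2-fold, the test recovered 86.7% for Anillin 4N against control 4N (12392 genes run), 86.7% for Anillin 4N against Anillin 2N (12387 genes), 86.7% for control 4N against control 2N (12381 genes), 85.6% for Anillin 2N against control 2N (12369 genes) and 79.4% for the interaction (12370 genes). In the same order it recovered 83.7%, 74.2%, 79.4%, 80.4% and 58.8% of genes changed 1.5-fold, and 4.57%, 6.55%, 2.41%, 3.01% and 4.97% of calls were false. A simulated 2-fold change was fitted at a median absolute log2 of 0.75 to 0.79. A simulated list with raised members was called, and 0 of 20 unchanged lists were. Because simulated genes varied independently, this does not test how correlation between genes affects list calls.

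Libraries of the same group had Pearson's r of 0.981 to 0.992 across genes on the log2 scale, and no pair agreed within sampling noise, with a chi-square per gene of 2.38 to 14.5. The first and second principal components held 51.0% and 11.1% of the variance. The labels give no batch or day. The alternatives were pseudocounts of 0.1 and 1, no filter and a mean RPKM of at least 1, median-of-ratios and quantile scaling, a fit of only the 2 groups compared, limma without the mean-variance trend, library quality weights, and leaving out each library in turn. Thinning of every library to the shallowest was added after the data had been seen. The median log2 change over all genes moved by less than 0.1 under either scaling.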

Results

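Polyadenylated or total RNA of sorted RPE1 cells was sequenced in 12 libraries, 3 for each combination of siRNA (non-targeting control or Anillin) and DNA content (2N or 4N). Reads in genes numbered 46031072, 27991710 and 61760450 in the control 2N libraries and 24943099, 46356779 and 45855303 in control 4N. They numbered 46980285, 40004576 and 22276820 in Anillin 2N and 17679989, 17412742 and 38854134 in Anillin 4N. Cells sorted at 2N are mostly in G1. The 4N gate of a control culture holds cells in G2 and mitosis, and after a cytokinesis failure it can also hold G1 cells with a doubled genome. Mitochondrial genes took 3.31% to 4.54% of reads and protein-coding genes 92.4% to 93.1%.

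ANLN (ENSG00000011426) lies on chromosome 7 from 36389806 to 36453791 on the plus strand of GRCh38, a protein-coding gene with a span of 63986 bases. Its level was 1.88, 1.25 and 1.67 RPKM in the control 2N libraries and 8.42, 7.45 and 7.98 in control 4N. It was 0.0850, 0.0582 and 0.0396 in Anillin 2N and 0.0989, 0.0855 and 0.0700 in Anillin 4N, so every Anillin siRNA library lay below every control library. ANLN fell by 3.85 ± 0.10 on the log2 scale among 4N cells (adjusted p = 1.69e-08) and by 1.89 ± 0.10 among 2N cells (adjusted p = 5.08e-06). On recovered reads, where no fixed RPKM is added, it fell by 6.61 and 4.67.

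**Figure D1:**
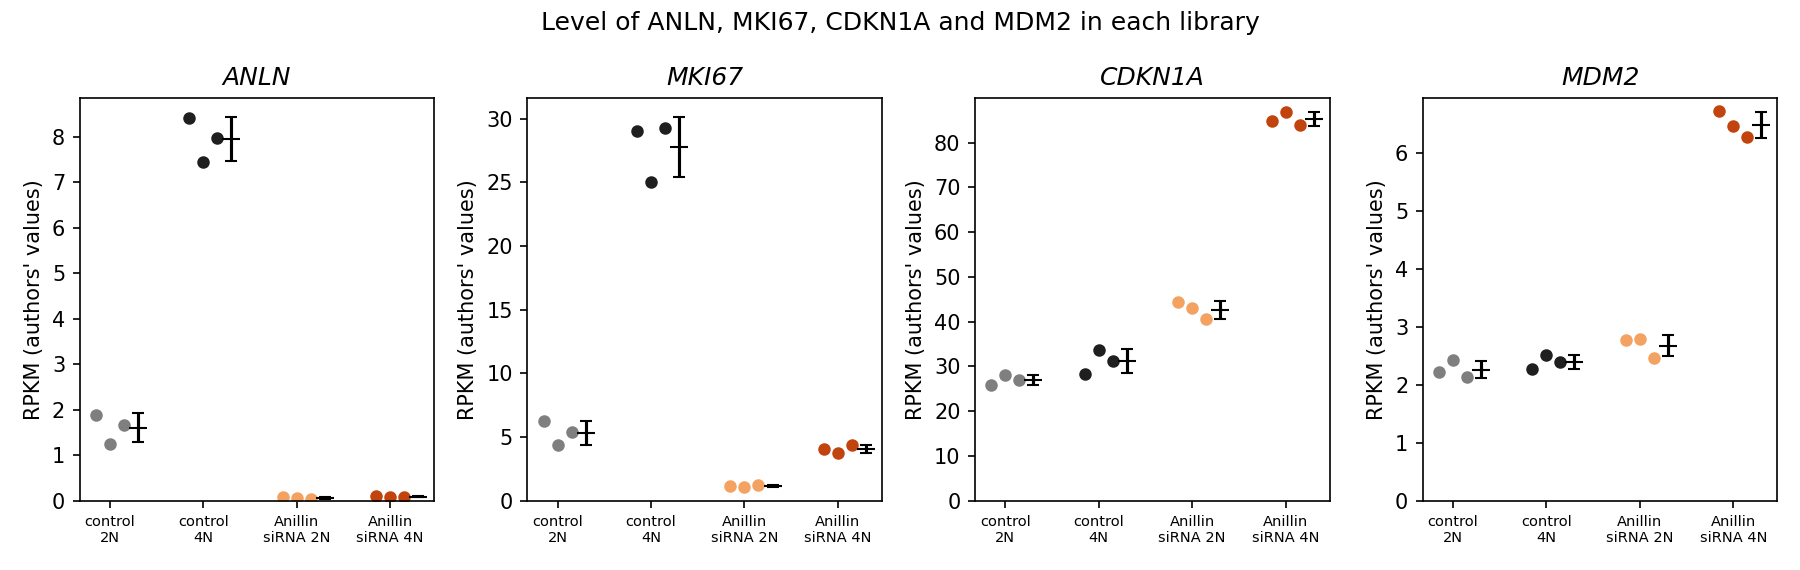
RPKM (linear axis from 0) of ANLN, MKI67, CDKN1A and MDM2 in each of the 12 libraries by group, each point a library, with the group mean and SD beside the points. ANLN reached 7.95 RPKM in control 4N and stayed below 0.1 in all Anillin siRNA libraries, while CDKN1A rose to 85.2 and MDM2 to 6.49 RPKM in Anillin 4N.

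The main comparison asked how cells sorted at 4N after Anillin siRNA differ from the 4N cells of control cultures. Genes of mitosis were lower and targets of p53 higher. All 55 measured genes of the G2/M list fell, also when adjusted over the list alone, with a median log2 change of -2.12 (camera adjusted p = 3.12e-32, and adjusted p = 0.176 with an estimated correlation). TOP2A, which untangles replicated DNA, fell from 42.6 ± 1.35 to 4.52 ± 0.194 RPKM (n = 3 and 3, log2 change -3.10 ± 0.07, adjusted p = 1.47e-08), and UBE2C, a ubiquitin-conjugating enzyme that works with the anaphase-promoting complex, from 48.8 ± 4.20 to 5.42 ± 0.365 RPKM (-3.06 ± 0.14, adjusted p = 1.82e-07). The other largest falls after ANLN were those of the mitotic kinase CDK1 (-2.87 ± 0.10), NEK2 (-2.81 ± 0.10) and BIRC5 (-2.72 ± 0.14). MKI67, a marker of cycling cells, changed by -2.64 ± 0.11 and cyclin B1 (CCNB1) by -2.32 ± 0.11. Of 32 measured genes of G1/S and DNA replication, 31 fell (31 when adjusted over the list alone), with a median of -1.05 (camera adjusted p = 8.76e-12, and adjusted p = 0.274 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, changed by -2.45 ± 0.16 and the flap endonuclease FEN1 by -1.77 ± 0.16. On recovered reads the medians of G2/M and G1/S genes were -2.65 and -1.62, with 55 and 49 members measured.

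Of 38 measured p53 targets, 34 rose among 4N cells after Anillin siRNA (35 when adjusted over the list alone) and 4 did not pass. Their median was 0.62 (camera adjusted p = 8.27e-20). The call held with an estimated correlation (adjusted p = 0.0276). The antiproliferative gene BTG2 rose from 3.07 ± 0.213 to 10.5 ± 0.63 RPKM (log2 change 1.63 ± 0.06, adjusted p = 5.16e-08). CDKN1A, which encodes the CDK inhibitor p21, rose from 31.1 ± 2.70 to 85.2 ± 1.56 RPKM (1.44 ± 0.06, adjusted p = 1.11e-07), and MDM2, the ubiquitin ligase of p53, from 2.40 ± 0.125 to 6.49 ± 0.222 RPKM (1.27 ± 0.06, adjusted p = 1.08e-07). BMF, a proapoptotic gene outside the list, rose by 1.62 ± 0.08, and an unnamed gene (ENSG00000117289) by 1.63 ± 0.21. The remaining 3 of the 6 largest rises were unnamed features with spans of 71 to 300 bases at 2.13, 2.08 and 2.02. The first and the last of these lost their call without control 4N replicate 2 (adjusted p = 0.0801 and 0.0872), Anillin 4N replicate 1 (0.0638 and 0.0640) or Anillin 4N replicate 3 (0.0713 and 0.0843), and the first also without control 4N replicate 3 (0.0512). Both were lost without a filter (0.0610 and 0.0682).

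Of 27 measured genes of cytokinesis and septins, 21 fell (22 when adjusted over the list alone), among them CEP55 (-2.60 ± 0.12) and PRC1 (-2.33 ± 0.12), which act at the midbody and midzone. MYL9 (0.26) and SEPTIN6 (0.10) rose. SEPTIN6 lost its call without control 4N replicate 1 or 3 (adjusted p = 0.0731 and 0.0614), Anillin 4N replicate 1 or 3 (0.0519 and 0.0723) or with only the 2 groups fitted (0.0770). Of 17 centrosome and centriole genes 12 fell (13 when adjusted over the list alone), including PLK4, the kinase that starts centriole duplication (-1.55 ± 0.08), and gamma-tubulin (TUBG1, -1.05 ± 0.13). PIDD1 (0.44) and CEP250 (0.26) rose. Of 24 cholesterol synthesis genes 19 fell (19 when adjusted over the list alone), with TMEM97 at -0.85 ± 0.09 and ACAT2 at -0.79 ± 0.06. The medians of these lists were -0.25, -0.43 (-0.86 on recovered reads, 22 members) and -0.47, with camera adjusted p = 6.32e-06, 0.000922 and 5.84e-06. With an estimated correlation, adjusted p = 0.176, 0.176 and 0.167.

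Among 28 genes of the TGF-beta response and extracellular matrix, 20 rose (20 when adjusted over the list alone), with SPARC at 1.04 ± 0.09. THBS1 (-0.73) and VIM (-0.19) fell. Of 12 replication-dependent histones 7 rose (7 when adjusted over the list alone), among them H2AC6 (0.94 ± 0.12) and H1-2 (0.66 ± 0.08). HIST2H3PS2 fell (-0.87). Of 32 genes of the ATF4 and unfolded protein response, 18 fell (19 when adjusted over the list alone), led by the amino acid transporter SLC7A5 (-1.07 ± 0.10) and PSAT1 of serine synthesis (-0.98 ± 0.06). SESN2 (0.52), CEBPB (0.37), DNAJB9 (0.33), VEGFA (0.30) and VLDLR (0.26) rose. DNAJB9 lost its call without control 4N replicate 1 or 3 or Anillin 4N replicate 1 (adjusted p = 0.0764, 0.0551 and 0.0682). Of 18 heat shock genes 12 fell (12 when adjusted over the list alone), with HSP90AA1 at -0.88 ± 0.06 and HSPD1 at -0.62 ± 0.06. HSPA4L rose (0.12), a call lost without control 4N replicate 1 or 2 or Anillin 4N replicate 2 or 3 (adjusted p = 0.117, 0.0621, 0.0652 and 0.119), with a pseudocount of 0.1 (0.0521) and with only the 2 groups fitted (0.0745). Of 14 housekeeping genes 11 fell (11 when adjusted over the list alone), including YWHAZ (-0.63 ± 0.04) and PGK1 (-0.52 ± 0.05). B2M rose (0.34). Medians of the 5 lists were 0.25, 0.35, -0.27, -0.37 and -0.35, with camera adjusted p = 5.84e-06, 0.0153, 0.00968, 0.00712 and 0.00868. These calls were lost with an estimated correlation, at adjusted p = 0.274, 0.176, 0.176, 0.326 and 0.317. The histone call was also lost with quantile scaling (adjusted p = 0.0722). On recovered reads the histone median was 0.59 (16 members), and with quantile scaling that of the ATF4 list was -0.14.

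Cyclin D1 (CCND1) was at 0.02 ± 0.09 (adjusted p = 0.888). Of 17 G1 cyclins and CDK inhibitors 10 fell (10 when adjusted over the list alone), with the CDK inhibitors CDKN3 at -1.80 ± 0.09 and CDKN2D at -1.47 ± 0.11. CDKN1C (0.80 ± 0.12), CDKN1B (0.30 ± 0.05) and CDKN2B (0.20) rose, and the list did not pass (camera adjusted p = 0.0901). CDKN2B lost its call without control 4N replicate 1 (adjusted p = 0.156, at 0.13) or 3 (0.0878), without any 1 Anillin 4N library (0.0684 to 0.102), without a filter (0.0863) and with only the 2 groups fitted (0.0865). That list passed as lower with voom (0.00999) and with fry (5.03e-06). The YAP targets CCN1 (CYR61) and CCN2 (CTGF) were at 0.37 ± 0.09 (adjusted p = 0.00621) and 0.39 ± 0.14 (adjusted p = 0.0379). CCN2 was not past the threshold when any 1 of the 6 libraries was left out (adjusted p = 0.0566 to 0.0992) or without a filter (0.0897). CCNE2 changed by -0.35 ± 0.06 and GAPDH by -0.32 ± 0.08, both lost with quantile scaling (adjusted p = 0.107 and 0.0623), and ACTB by -0.43 ± 0.06. CCNE2 lay below the pseudocount, at 0.261 RPKM in control 4N and 0.0982 in Anillin 4N. The ratio of these means was 0.38, against 0.80 for GAPDH. The other lists not past the threshold had camera adjusted p = 0.399 (YAP/TAZ-TEAD targets), 0.949 (inflammatory genes), 0.949 (immediate early genes, whose median of -0.06 and test differ in sign), 0.175 (mitochondrial messenger RNAs) and 0.0502 (interferon-stimulated genes). The last passed without control 4N replicate 2 (0.0374) or Anillin 4N replicate 3 (0.0480), with a pseudocount of 0.1 (0.0490) and with fry (0.00922), and the mitochondrial list without control 4N replicate 2 (0.0499) or Anillin 4N replicate 2 (0.0390). In all, 2582 genes were higher and 4056 lower in Anillin 4N than in control 4N, 82 and 335 of them at least 2-fold (681 and 835 on recovered reads). Quantile scaling gave 3505 and 3182, so the share of higher calls moved from 38.9% to 52.4%. On recovered reads 4652 genes were higher and 5295 lower, and of the 6638 calls, 95.3% of those also tested on reads were called in the same direction.

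The comparison of 4N with 2N cells within the Anillin siRNA cultures had fewer changed genes. Of the 55 G2/M genes 51 rose (54 when adjusted over the list alone), with a median of 0.72, or 1.46 on recovered reads (camera adjusted p = 1.23e-67, and adjusted p = 0.0628 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, rose from 2.79 ± 0.138 to 10.7 ± 0.245 RPKM (log2 change 1.77 ± 0.15, adjusted p = 0.000204), and UBE2C (1.71 ± 0.14), KIF20A (1.71 ± 0.13), TROAP (1.57 ± 0.11), CDCA3 (1.57 ± 0.12) and MKI67 (1.46 ± 0.11) were the other largest rises. CCNB1 rose by 1.16 ± 0.11. Of the 38 p53 targets 29 rose (32 when adjusted over the list alone) and 9 did not pass, with a median of 0.41 (camera adjusted p = 1.78e-39). The call held with an estimated correlation (adjusted p = 0.00273). FDXR, a mitochondrial reductase, rose from 2.83 to 7.46 ± 0.466 RPKM (1.26 ± 0.06, adjusted p = 8.58e-06), MDM2 from 2.67 ± 0.184 to 6.49 ± 0.222 (1.14 ± 0.06, adjusted p = 8.58e-06) and CDKN1A from 42.7 ± 2.02 to 85.2 ± 1.56 (0.99 ± 0.06, adjusted p = 5.09e-05). ANLN was at 0.06 ± 0.10 (adjusted p = 0.802).

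Centrosome genes as a list were higher in Anillin 4N than in Anillin 2N cells (median 0.07, or 0.16 on recovered reads with 22 members, camera adjusted p = 0.000114, and adjusted p = 0.0851 with an estimated correlation), with CCP110 (0.41), PLK4 (0.36), PIDD1 (0.31) and CEP250 (0.26) past the threshold and 5 when adjusted over the list alone. PLK4 was not called when any 1 of the 6 libraries was left out (adjusted p = 0.0598 to 0.117). PIDD1 was not called without replicate 2 or 3 of Anillin 2N (0.0954 and 0.0939) or of Anillin 4N (0.0994 and 0.0891), and CEP250 was not called without Anillin 2N replicate 1 or 2 (0.0550 and 0.0612) or Anillin 4N replicate 3 (0.0553). Targets of YAP were lower as a list (median -0.07, camera adjusted p = 2.14e-05, and adjusted p = 0.286 with an estimated correlation), a call lost with fry (0.0503). Their median was -0.13 and -0.02 without Anillin 2N replicate 1 and 3, -0.12 without Anillin 4N replicate 3 and -0.10 with quantile scaling. ANKRD1 (-0.69 ± 0.10), CCN2 (-0.65 ± 0.14), TGFB2 (-0.46), IGFBP3 (-0.45) and CCN1 (-0.42 ± 0.09) fell, with 8 lower and 1 higher when adjusted over the list alone. The calls of CCN2 and CCN1 were lost when any 1 of the 6 libraries was left out (adjusted p = 0.0550 to 0.114 and 0.0671 to 0.114), and those of TGFB2 and IGFBP3 with only the 2 groups fitted (0.0532 and 0.0773).

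Lists of TGF-beta response and matrix genes (median -0.13), inflammatory genes (-0.19), histones (-0.30), interferon-stimulated genes (-0.05) and mitochondrial messenger RNAs (-0.10) were also lower in Anillin 4N than in Anillin 2N cells, with camera adjusted p = 2.40e-06, 3.58e-06, 1.32e-05, 0.00107 and 0.00692. These calls were lost with an estimated correlation, at adjusted p = 0.286, 0.154, 0.0507, 0.0851 and 0.433. The smooth muscle genes ACTA2 (-0.64 ± 0.11) and TAGLN (-0.51 ± 0.06) fell, as did the chemokine CCL2 (-0.68 ± 0.11), the histone H4C8 (-0.43 ± 0.07), CHI3L1 (-0.64 ± 0.09) and an unnamed transcript (ENSG00000261114, -0.76 ± 0.13). Other members past the threshold lost their calls when single libraries were left out, which also leaves fewer libraries to test. In the fits without a call, log2 changes moved little for TPM1 (-0.27 in each) and IFIT5 (-0.21 to -0.17), and more for HIST2H3PS2 (-0.66 to -0.49). TPM1 (-0.28) was lost without Anillin 2N replicate 2 or Anillin 4N replicate 1 or 2 (adjusted p = 0.0664, 0.0562 and 0.0623), and H2BC12 (-0.35) without Anillin 2N replicate 2 or 3 (0.0516 and 0.0501). The call was lost for DTX3L (-0.18) without Anillin 2N replicate 2 or 3 or Anillin 4N replicate 1 or 2 (0.0700 to 0.0952) and for HIST2H3PS2 (-0.58) when any library but Anillin 4N replicate 3 was left out (0.0560 to 0.152). SOD2 (-0.15) and IFIT5 (-0.20) were not called when any 1 of the 6 was left out (0.0698 to 0.149 and 0.0801 to 0.152). Adjusted over each list alone, 7 matrix genes, 6 inflammatory genes, 3 histones and 2 interferon-stimulated genes were lower, and 2 matrix genes higher. The mitochondrial call was lost with quantile scaling (adjusted p = 0.65), with fry (0.313), and without replicate 2 of Anillin 2N (0.125) or of Anillin 4N (0.219), and the matrix call with fry (0.0588). The matrix median was -0.08 without Anillin 2N replicate 3, the mitochondrial one -0.02 without Anillin 4N replicate 2, and that of interferon-stimulated genes -0.16 on recovered reads (35 members).

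G1/S genes as a list did not differ by the test between the Anillin fractions (median 0.02, camera adjusted p = 0.826). CCNE2, one of them, was at -0.28 ± 0.06 (adjusted p = 0.0397), a call lost when any 1 of the 6 libraries was left out (adjusted p = 0.0991 to 0.114). Its mean was 0.228 RPKM in Anillin 2N and 0.0982 in Anillin 4N, both below the pseudocount, with a ratio of 0.43. Over the other settings and left-out libraries its log2 change lay between -1.21 and -0.16. Values of CCND1 (-0.08 ± 0.09), ACTB (-0.06 ± 0.06) and GAPDH (0.03 ± 0.08) had adjusted p = 0.725, 0.695 and 0.888. The remaining 7 lists had camera adjusted p between 0.06 and 0.826, and of these cholesterol synthesis passed without Anillin 4N replicate 2 (0.0257) and with voom (0.019), G1 cyclins and CDK inhibitors with fry (0.0161), and the ATF4 list without Anillin 2N replicate 2 (0.0219) or Anillin 4N replicate 3 (0.0453). Other settings ended calls of genes named for the Anillin fractions. Without a filter they were those of CCN1, CCN2, CCNE2, HIST2H3PS2, IFIT5, PIDD1, PLK4 and SOD2 (adjusted p = 0.0607 to 0.102), and with only the 2 groups fitted those of CCNE2, DTX3L, H2BC12, HIST2H3PS2, IFIT5, PIDD1, PLK4 and SOD2 (0.0544 to 0.102). Quantile scaling ended those of CCN1, CCN2, CCNE2 and TPM1 (0.0644 to 0.236), and a pseudocount of 1 those of CCNE2 and HIST2H3PS2 (0.0703 and 0.0583). IFIT5 was also lost with voom, log2 RPM and median-of-ratios scaling (0.065, 0.0545 and 0.0573), and DTX3L with voom (0.0548). In all, 336 genes were higher and 125 lower in Anillin 4N than in Anillin 2N, 27 and 2 of them at least 2-fold (136 and 19 on recovered reads). Quantile scaling gave 309 and 194, moving the share of higher calls from 72.9% to 61.4%. On recovered reads 576 were higher and 329 lower, and of the 461 calls, 88.8% of those also tested on reads were called in the same direction. Without Anillin 2N replicate 2 or 3 the count was 241 and 300, and without Anillin 4N replicate 2 or 3 it was 243 and 306.

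In control cultures, the same comparison of 4N with 2N cells gives the difference between G2/M and mostly G1 cells. All 55 G2/M genes rose, also when adjusted over the list alone, with a median of 2.03, or 2.63 on recovered reads (camera adjusted p = 1.16e-46, and adjusted p = 0.149 with an estimated correlation). UBE2C rose from 4.06 ± 1.02 to 48.8 ± 4.20 RPKM (log2 change 3.46 ± 0.14, adjusted p = 1.14e-07), followed by the mitotic kinase PLK1 (2.92 ± 0.10), TOP2A (2.90 ± 0.07), TROAP (2.88 ± 0.11) and CDK1 (2.82 ± 0.10). MKI67 (2.29 ± 0.11), CCNB1 (2.34 ± 0.11) and ANLN (2.02 ± 0.10) rose as well. Of the G1/S genes 21 rose (22 when adjusted over the list alone), with RRM2 at 1.47 ± 0.16 and ORC6 at 1.24 ± 0.09. CCNE2 (-0.69 ± 0.06, ratio of means 0.36) and UNG (-0.56 ± 0.07) fell. Of 27 cytokinesis genes 16 rose (16 when adjusted over the list alone), with CEP55 at 2.20 ± 0.12 and KIF23 at 2.19 ± 0.10. MYL9 (-0.29) and MYH9 (-0.19) fell, and MYH9 lost its call without replicate 1, 2 or 3 of control 2N (adjusted p = 0.0701, 0.0596 and 0.111) or replicate 1 or 2 of control 4N (0.118 and 0.113), without a filter (0.0732), with median-of-ratios scaling (0.0504), library quality weights (0.0594) and only the 2 groups fitted (0.0626). Of 17 centrosome genes 13 rose (13 when adjusted over the list alone), with PLK4 at 1.42 ± 0.08 and CNTROB at 1.06 ± 0.06. PIDD1 (-0.25) and OFD1 (-0.20) fell, and OFD1 lost its call without control 2N replicate 2 or control 4N replicate 3 (0.0542 and 0.0554). These lists had medians of 0.53, 0.17 (0.066 with quantile scaling) and 0.40 (0.74 on recovered reads, 22 members) and camera adjusted p = 0.000222, 0.000279 and 5.92e-06. With an estimated correlation, adjusted p = 0.53, 0.272 and 0.149.

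Among p53 targets, 23 of 38 did not pass between control 4N and control 2N cells and the others went both ways (median 0.03, camera adjusted p = 0.976, and 0.0198 with fry). MDM2 was at 0.07 ± 0.06 (adjusted p = 0.339), and CDKN1A at 0.20 ± 0.06 (adjusted p = 0.0313), a call lost without control 2N replicate 1 or 3 (0.0919 and 0.0688) or control 4N replicate 2 or 3 (0.0941 and 0.0811) with quantile scaling (0.659), without a filter (0.061) and with only the 2 groups fitted (0.0978). Of 17 G1 cyclins and CDK inhibitors 9 rose (11 when adjusted over the list alone), with CDKN2D at 1.66 ± 0.11 and CDKN3 at 1.47 ± 0.09. CDKN2B fell (-0.50). Of 18 heat shock genes 12 rose (14 when adjusted over the list alone), with HSPA8 at 0.51 ± 0.04 and HSP90AA1 at 0.51 ± 0.06. DNAJB4 fell (-0.28). Of 14 housekeeping genes 6 rose (9 when adjusted over the list alone), among them HPRT1 (0.26 ± 0.05). The medians were 0.20, 0.24 and 0.17, with camera adjusted p = 0.00182, 0.00269 and 0.0178. These calls were lost with an estimated correlation, at adjusted p = 0.209, 0.339 and 0.408, and the housekeeping call was lost with quantile scaling (0.0769). With that scaling the medians were 0.12, 0.12 and 0.076, and the housekeeping median was 0.11 without control 2N replicate 2.

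Inflammatory and matrix genes were lower in control 4N than in control 2N cells. Of 15 inflammatory genes 11 fell (11 when adjusted over the list alone), with interleukin-1 beta (IL1B) at -0.87 ± 0.07 and cyclooxygenase 2 (PTGS2) at -0.87 ± 0.09. Of 28 matrix genes 16 fell (18 when adjusted over the list alone), with ACTA2 at -0.59 ± 0.11. PMEPA1 (0.28) and VIM (0.24) rose. Of 20 YAP targets 12 fell (13 when adjusted over the list alone), with ANKRD1 at -1.25 ± 0.10, CCN2 at -0.92 ± 0.14 and CCN1 at -0.75 ± 0.09. AXL rose (0.32), a call lost without control 2N replicate 2 or control 4N replicate 1 or 3 (adjusted p = 0.0889, 0.0972 and 0.0927), with quantile scaling (0.139), without a filter (0.0616) and with only the 2 groups fitted (0.0942). Of 20 interferon-stimulated genes 10 fell (12 when adjusted over the list alone), with IFIT2 at -0.45 ± 0.06 and IFIT5 at -0.37 ± 0.04. OAS3 (0.44) and IFIT1 (0.27) were among the 3 that rose. Medians of the 4 lists were -0.54, -0.24, -0.19 and -0.13 (the last -0.23 on recovered reads with 35 members and -0.21 with quantile scaling), with camera adjusted p = 1.53e-06, 3.67e-05, 1.59e-05 and 0.00136. With an estimated correlation, adjusted p = 0.15, 0.339, 0.272 and 0.149.

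Of 12 histones, H2BC21 (-0.89 ± 0.15), H2AC6 (-0.64 ± 0.12), H4C8 (-0.39), H1-2 (-0.26) and H2BC12 (-0.23) fell between control 2N and control 4N cells (6 when adjusted over the list alone), with a median of -0.25, or -0.43 on recovered reads with 16 members (camera adjusted p = 0.00339, and adjusted p = 0.15 with an estimated correlation). The call of H1-2 was lost without control 2N replicate 1 or 2 (adjusted p = 0.0997 and 0.103) or control 4N replicate 1 or 3 (0.123 and 0.0502), without a filter (0.0705), with voom (0.073) and with only the 2 groups fitted (0.0909). Of 22 immediate early genes, FOSL1 (1.07 ± 0.14) and IER2 (0.36) rose, and ZFP36 (-0.49), KLF6 (-0.41 ± 0.07), IER3 (-0.39), DUSP6 (-0.35) and DUSP5 (-0.35) fell (2 higher and 4 lower when adjusted over the list alone). ZFP36 was not called when any 1 of the 6 libraries was left out (0.0637 to 0.0884), and IER3 not when any but control 2N replicate 2 was left out (0.0587 to 0.0894), and neither without a filter (0.0791 and 0.0699). DUSP5 was not called without control 2N replicate 3 or control 4N replicate 1, 2 or 3 (0.0711 to 0.117), without a filter (0.105) or with only the 2 groups fitted (0.113), and IER2 not with quantile scaling (0.0579). That list had a median of -0.17, or -0.28 with quantile scaling (camera adjusted p = 0.0158, and adjusted p = 0.461 with an estimated correlation), and its call was lost with voom (0.0513) and with fry (0.181). MT-CO1 fell (-0.22), not without control 2N replicate 2 or control 4N replicate 1 (0.0517 and 0.0532) or without a filter (0.262), in a list of mitochondrial messenger RNAs at a median of -0.10 (camera adjusted p = 0.0358, and adjusted p = 0.53 with an estimated correlation). The mitochondrial call was lost with quantile scaling (0.432), voom (0.124) and fry (0.27), and without control 2N replicate 1 or 2 (0.0713 and 0.0514) or control 4N replicate 1 or 3 (0.122 and 0.0997). Its median was -0.04 and -0.17 without control 4N replicate 1 and 2.

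Cholesterol synthesis and the ATF4 list did not pass in controls (camera adjusted p = 0.999 and 0.956), and for both the median (0.05 and 0.002) and the test differ in sign. CCND1 (0.13 ± 0.09), ACTB (0.17 ± 0.06) and GAPDH (0.18 ± 0.08) had adjusted p = 0.277, 0.0558 and 0.0952. In all, 3079 genes were higher and 1703 lower in control 4N than in control 2N, 224 and 28 of them at least 2-fold (478 and 267 on recovered reads). An unnamed feature of 91 bases (ENSG00000221323) rose by 2.83 ± 0.52. The 6 largest falls were all unnamed features of 76 to 300 bases, from -2.52 to -1.27, whose calls were each lost without at least 1 library (adjusted p up to 0.13). Quantile scaling gave 2096 and 2465, moving the share of higher calls from 64.4% to 46.0%. On recovered reads 4248 were higher and 3890 lower, and of the 4782 calls, 97.4% of those also tested on reads were called in the same direction.

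**Figure D2:**
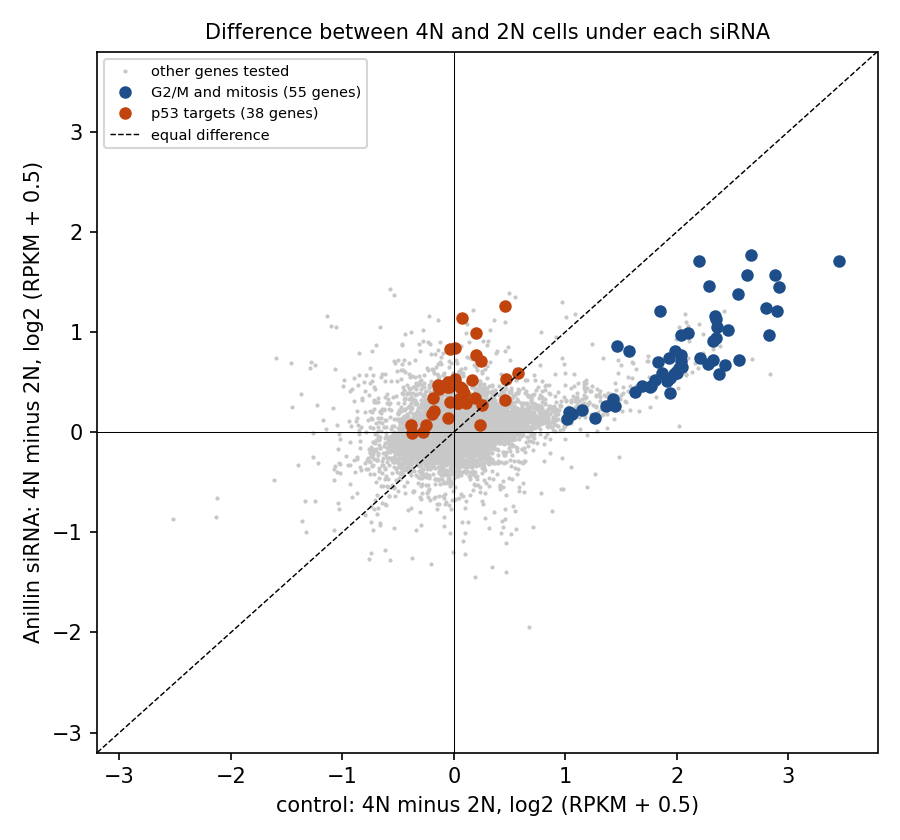
Log2 change (RPKM + 0.5) from 2N to 4N cells in Anillin siRNA cultures (vertical axis) against that in control cultures (horizontal axis), 1 point per gene tested, with the 55 G2/M genes and 38 p53 targets coloured and a dashed line of equal difference. G2/M genes lie to the right below the line (medians 2.03 in controls and 0.72 after Anillin siRNA, or 2.63 and 1.46 on recovered reads), and most p53 targets lie above it (medians 0.03 and 0.41).

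Among cells sorted at 2N, Anillin siRNA lowered both lists of cell cycle genes and raised p53 targets. All 32 measured G1/S genes fell, also when adjusted over the list alone (median -0.69, or -1.13 on recovered reads with 49 members, camera adjusted p = 1.17e-15, and adjusted p = 0.266 with an estimated correlation), with RRM2 at -1.69 ± 0.16 and thymidine kinase (TK1) at -1.22 ± 0.14. Of the 55 G2/M genes 51 fell (53 when adjusted over the list alone), with a median of -0.72, or -1.55 on recovered reads (camera adjusted p = 2.28e-27, and adjusted p = 0.245 with an estimated correlation). BIRC5, which encodes survivin, fell by 2.08 ± 0.14 (adjusted p = 1.97e-05), KIF20A by 1.82 ± 0.13, CDC20 by 1.68 ± 0.15 and CCNB1 by 1.14 ± 0.11, and the pseudogene HMGN2P32 by 1.67 ± 0.18. MKI67 fell from 5.32 ± 0.951 to 1.15 ± 0.0795 RPKM (adjusted p = 1.25e-05). Of 38 p53 targets 31 rose (32 when adjusted over the list alone), with a median of 0.32 (camera adjusted p = 8.69e-16). The call held with an estimated correlation (adjusted p = 0.0276). TP53INP1 rose by 0.76 ± 0.12, BTG2 by 0.76 ± 0.06 and CDKN1A by 0.65 ± 0.06 (27.0 ± 1.13 to 42.7 ± 2.02 RPKM, adjusted p = 0.000121), and PLK2 fell (-0.43 ± 0.08). MDM2 was at 0.20 ± 0.06 (adjusted p = 0.0212), not past the threshold without control 2N replicate 1 or 3 (0.0685 and 0.0788) or Anillin 2N replicate 1 or 2 (0.0705 and 0.0790) or with only the 2 groups fitted (0.0739).

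Of the genes with the largest rises in Anillin 2N cells, HMOX1, the heme oxygenase induced by oxidative stress, rose from 3.77 to 10.8 RPKM (log2 change 1.40 ± 0.10, adjusted p = 2.12e-05). CHI3L1 (1.10 ± 0.09), SCG2 (1.09 ± 0.13), the laminin chain LAMA5 (0.996 ± 0.07), ANGPTL2 (0.97 ± 0.05) and the unnamed gene that also rose among 4N cells (ENSG00000117289, 1.61 ± 0.21) were the others. Of 24 cholesterol synthesis genes 20 fell (23 when adjusted over the list alone), with INSIG1 at -0.72 ± 0.11 and MSMO1 at -0.63 ± 0.05 (median -0.46, camera adjusted p = 4.46e-13). The call held with an estimated correlation (adjusted p = 0.0276). Of 28 matrix genes 17 rose (17 when adjusted over the list alone), with SPARC at 0.83 ± 0.09 and the basement membrane collagen COL4A1 at 0.56 ± 0.09. THBS1 fell (-0.77 ± 0.14). Of 32 genes of the ATF4 list 15 fell (17 when adjusted over the list alone), with DDIT4 at -0.80 ± 0.08 and SLC7A5 at -0.77 ± 0.10. VLDLR (0.27) and SESN2 (0.27) rose. Of 27 cytokinesis genes 12 fell (13 when adjusted over the list alone), with CEP55 at -1.49 ± 0.12 and PRC1 at -1.34 ± 0.12. MYL9 (0.39) and SEPTIN6 (0.15) rose, SEPTIN6 not with only the 2 groups fitted (adjusted p = 0.0549). Medians of the last 3 lists were 0.24 (0.37 on recovered reads, 35 members), -0.17 and -0.10, with camera adjusted p = 7.34e-07, 0.000498 and 0.000498. These calls were lost with an estimated correlation, at adjusted p = 0.266, 0.13 and 0.266.

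The inflammatory genes CSF2 (-0.90 ± 0.20), CXCL2 (-0.89 ± 0.14), interleukin-6 (IL6, -0.88), IL1B (-0.69) and CXCL3 (-0.58) fell in Anillin 2N cells, and 6 of 15 were lower when adjusted over the list alone. Of 12 histones, H2AC7 (0.66 ± 0.16), H2AC6 (0.56 ± 0.12), H1-2 (0.45), H4C8 (0.43) and H2BC12 (0.41) rose (5 when adjusted over the list alone). Of 18 heat shock genes 8 fell (9 when adjusted over the list alone), with HSPD1 at -0.49 ± 0.06 and HSP90AA1 at -0.45 ± 0.06. CRYAB rose (0.27). Of 17 centrosome genes 7 fell (8 when adjusted over the list alone), with PLK4 at -0.49 ± 0.08. Of 14 housekeeping genes 7 fell (7 when adjusted over the list alone), with PGK1 at -0.38 ± 0.05 and YWHAZ at -0.35 ± 0.04. B2M rose (0.30). Medians of these 5 lists were -0.29, 0.40, -0.17, -0.10 (-0.21 on recovered reads with 22 members) and -0.17, with camera adjusted p = 0.00497, 0.00286, 0.00983, 0.00720 and 0.0112. With an estimated correlation, adjusted p = 0.329, 0.14, 0.342, 0.253 and 0.329. The inflammatory call was lost with voom (adjusted p = 0.0720) and the centrosome call with quantile scaling (0.0554, median -0.06).

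CCNE2 fell by 0.75 ± 0.06 in Anillin 2N cells (ratio of means 0.31). Of 17 G1 cyclins and CDK inhibitors CDKN1C (0.55 ± 0.12), CDKN1B (0.23 ± 0.05) and RBL2 (0.15) rose, and CDKN3 (-0.93 ± 0.09), MYC (-0.59 ± 0.08), CDK2 (-0.37), CDKN2C (-0.24) and RB1 (-0.14) fell (3 and 5 when adjusted over the list alone), within a list that did not pass (camera adjusted p = 0.529). RBL2 and CDKN2C lost their calls without control 2N replicate 1 or 3 or Anillin 2N replicate 2 or 3 (adjusted p = 0.0590 to 0.0757 and 0.0556 to 0.0661), and CDK2 without control 2N replicate 1 or 3 or any 1 Anillin 2N library (0.0519 to 0.0792). With only the 2 groups fitted the calls of RBL2, CDK2, CDKN2C and RB1 were lost (0.0583, 0.0693, 0.0706 and 0.0691), as were those of CDK2 without a filter (0.0528) and of RB1 with quantile scaling (0.0693). ACTB was at -0.20 ± 0.06 (adjusted p = 0.0337), a call lost without control 2N replicate 1 or 3 or Anillin 2N replicate 1, 2 or 3 (0.0626 to 0.118), without a filter (0.08), with log2 RPM (0.0767) and with only the 2 groups fitted (0.0915). CCN2 (0.12 ± 0.14), CCN1 (0.04 ± 0.09), CCND1 (0.22 ± 0.09) and GAPDH (-0.17 ± 0.08) had adjusted p = 0.579, 0.778, 0.0889 and 0.137. The remaining lists had camera adjusted p = 0.242 (YAP/TAZ-TEAD targets), 0.103 (immediate early genes), 0.104 (mitochondrial messenger RNAs) and 0.125 (interferon-stimulated genes). Without Anillin 2N replicate 3 the first 3 passed (0.0199, 0.0195 and 0.0256), and immediate early genes also without control 2N replicate 1 (0.0261). In all, 1473 genes were higher and 2209 lower in Anillin 2N than in control 2N, 9 and 58 of them at least 2-fold (183 and 340 on recovered reads). Quantile scaling gave 1951 and 1900, moving the share of higher calls from 40.01% to 50.7%. On recovered reads 2782 were higher and 3620 lower, and of the 3682 calls, 97.1% of those also tested on reads were called in the same direction.

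Across the 12892 genes, the siRNA effect among 4N cells and that among 2N cells, which share no library, had Pearson's r = 0.652 and Spearman's rho = 0.644. Genes are not independent replicates, so no p-value is given. Of the genes higher in each, 1148 were shared where independent lists would share 295, and of those lower 1888 were shared where 695 would be, while 34 higher and 36 lower among 4N cells were called the opposite way among 2N cells. For the difference between 4N and 2N cells after Anillin siRNA and that in controls, r = 0.39 and rho = 0.342. There, 225 higher genes were shared where independent lists would share 80.3, and 85 lower genes where 16.5 would be, while 22 genes higher and 7 lower after Anillin siRNA were called the opposite way in controls, of 336 and 125 called.

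The interaction tested whether the difference between 4N and 2N cells depends on the siRNA, which is the same number as the dependence of the siRNA effect on the gate. For p53 targets it was positive: 25 of 38 were past the threshold (32 higher and 2 lower when adjusted over the list alone), with a median of 0.37 (camera adjusted p = 2.89e-20). The call held with an estimated correlation (adjusted p = 0.0257). MDM2 (1.07 ± 0.08, adjusted p = 3.25e-05), BTG2 (0.87 ± 0.08, adjusted p = 0.000168) and CDKN1A (0.79 ± 0.09, adjusted p = 0.000419) thus differed more between siRNAs among 4N than among 2N cells. For G2/M genes it was negative: 53 of 55 were past the threshold (55 when adjusted over the list alone), with a median of -1.28 (camera adjusted p = 3.09e-48, and adjusted p = 0.139 with an estimated correlation). The importin KPNA2 (-1.94 ± 0.12), CDK1 (-1.85 ± 0.14), CDCA8 (-1.84 ± 0.12), FAM83D (-1.81 ± 0.11) and the helicase PIF1 (-1.76 ± 0.10) had the largest negative values after ANLN (-1.96 ± 0.14). Of these, KPNA2 and ANLN, the target of the siRNA, are outside the G2/M list. CCNB1 was at -1.18 ± 0.15 and MKI67 at -0.83 ± 0.16. Of 27 cytokinesis genes 12 were negative (16 when adjusted over the list alone), with KIF23 at -1.56 ± 0.14 and RACGAP1 at -1.37 ± 0.10. Of 17 centrosome genes 11 were negative (12 when adjusted over the list alone), with PLK4 at -1.06 ± 0.11 and CNTROB at -0.95 ± 0.08. PIDD1 (0.56) and CEP250 (0.23) were positive, CEP250 not without control 2N replicate 1 or 3, control 4N replicate 1 or 2, Anillin 2N replicate 1 or 2, or Anillin 4N replicate 1, 2 or 3 (adjusted p = 0.0728 to 0.0931), or without a filter (0.0861). Of 32 G1/S genes 9 were negative (17 negative and 2 positive when adjusted over the list alone), with ORC6 at -1.07 ± 0.13. CCNE2 was positive (0.40). The medians of these 3 lists were -0.20 (-0.099 with quantile scaling), -0.34 (-0.52 on recovered reads, 22 members) and -0.40 (-0.26 without control 2N replicate 2), with camera adjusted p = 2.18e-06, 0.000102 and 8.53e-05. These calls were lost with an estimated correlation, at adjusted p = 0.237, 0.139 and 0.586, and the G1/S call was lost with fry (0.0593).

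The CDK inhibitors CDKN2D (-1.45 ± 0.15), CDKN2C (-1.10 ± 0.09) and CDKN3 (-0.88), with CDK2 (-0.85) and RB1 (-0.22), had negative interactions (5 of 17 in their list, also when adjusted over the list alone and a median of -0.14, camera adjusted p = 0.0118, and adjusted p = 0.416 with an estimated correlation). The inflammatory genes IL1B (0.62 ± 0.11) and PTGS2 (0.59 ± 0.12) were positive in a list of 15 with a median of 0.17 (2 when adjusted over the list alone, camera adjusted p = 0.0018, and adjusted p = 0.445 with an estimated correlation). With fry that list had adjusted p = 0.0603, and its median was 0.27 without Anillin 2N replicate 3 and with quantile scaling, and 0.28 on recovered reads (23 members). Among 20 YAP targets, ARHGEF17 (0.24 ± 0.06) and ANKRD1 (0.56 ± 0.14) were positive (2 when adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.00854, and adjusted p = 0.586 with an estimated correlation). The call of ANKRD1 was lost without control 2N replicate 2 or 3, control 4N replicate 1 or 3, Anillin 2N replicate 1, or Anillin 4N replicate 2 or 3 (adjusted p = 0.0563 to 0.0771) or without a filter (0.0725). The call of the list was lost without Anillin 2N replicate 1 (0.0698, median 0.06) and with fry (0.2), and its median was 0.15 without Anillin 2N replicate 3, with quantile scaling and on recovered reads (24 members). HSPA8 (-0.63 ± 0.06), HSP90AA1 (-0.43 ± 0.09), DNAJB1 (-0.42), HSPH1 (-0.30) and DNAJA1 (-0.27) were negative among heat shock genes (5 when adjusted over the list alone). That list (median -0.16, camera adjusted p = 0.0480, and adjusted p = 0.586 with an estimated correlation) lost its call without control 2N replicate 1 or 2, control 4N replicate 3, Anillin 2N replicate 1 or 2, or Anillin 4N replicate 1 or 3 (0.0558 to 0.111). It was also lost with a pseudocount of 1 (0.0530) and with quantile scaling (0.1, median -0.092), and its median was -0.088 without control 2N replicate 2. DNAJB1 was lost without control 2N replicate 1 or 2, any control 4N replicate, Anillin 2N replicate 1 or 2, or Anillin 4N replicate 2 or 3 (0.0680 to 0.0909), without a filter (0.0923) and with quantile scaling (0.198). CDKN3 was lost with voom (0.0614, at -0.52), HSPH1 with quantile scaling (0.0731) and CCNE2 with voom (0.434), log2 RPM (0.143) and a pseudocount of 0.1 (0.117).

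CCN1 (0.33 ± 0.13), CCN2 (0.27 ± 0.19), CCND1 (-0.21 ± 0.13), ACTB (-0.23 ± 0.09) and GAPDH (-0.15 ± 0.11) had no interaction past the threshold (adjusted p = 0.113, 0.39, 0.305, 0.11 and 0.398). Of the other lists, cholesterol synthesis had camera adjusted p = 0.359 (its median of -0.02 and test differ in sign), the ATF4 list 0.379 (0.0119 with fry), mitochondrial messenger RNAs 0.545 and histones 0.545. The mitochondrial median and mean (-0.0012 and 0.00045) differ in sign, as do those of histones (0.10 and -0.01). Housekeeping genes (0.0563) and matrix genes (0.113) passed without control 2N replicate 3 (0.0233 and 0.0233) or Anillin 2N replicate 3 (0.0220 and 0.00932), interferon-stimulated genes (0.113) without control 2N replicate 3 (0.0491), and immediate early genes (0.0602) without control 2N replicate 1, control 4N replicate 2, Anillin 2N replicate 3 or Anillin 4N replicate 2 (0.0237, 0.0405, 0.0124 and 0.0303). Housekeeping genes also passed with a pseudocount of 0.1 (0.0484), median-of-ratios scaling (0.0349) and voom (0.00808), and immediate early genes with quantile scaling (0.0219). In all, 636 genes had a positive and 1383 a negative interaction past the threshold, 24 and 133 of them of at least 1 on the log2 scale (137 and 216 on recovered reads). Quantile scaling gave 781 and 1099, moving the positive share from 31.5% to 41.5%. On recovered reads there were 1423 and 1837, and of the 2019 calls, 89.8% of those also tested on reads were called in the same direction. Without control 4N replicate 1 the count was 1295.

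**Figure D3:**
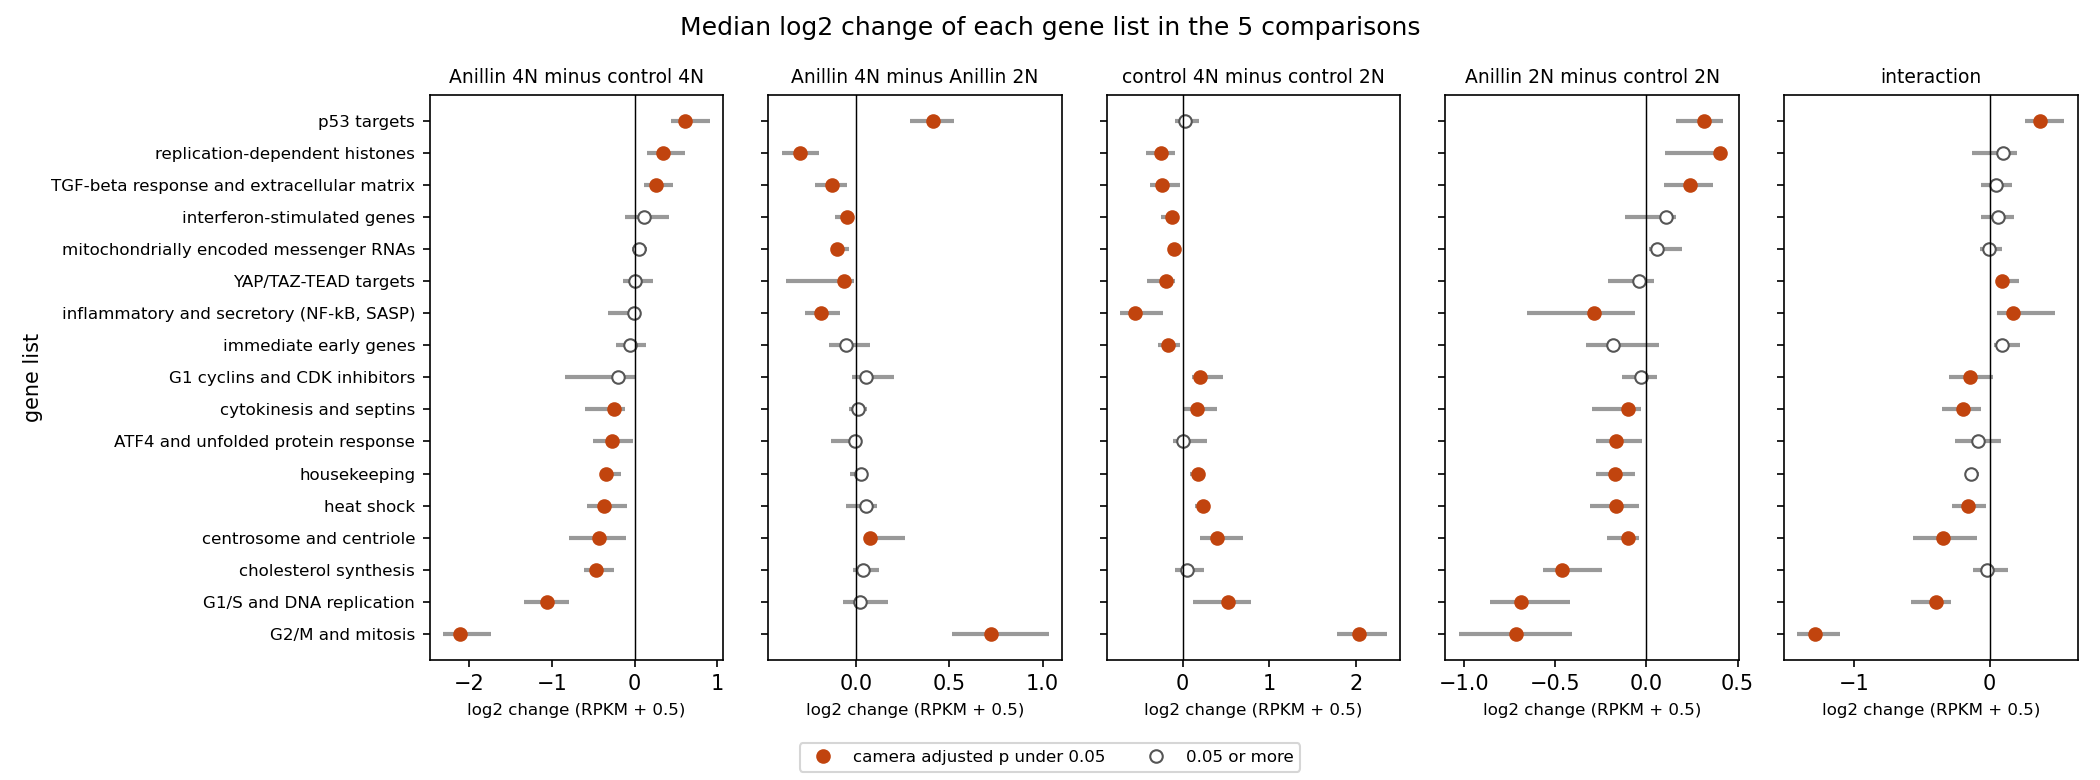
Median log2 change (RPKM + 0.5) of the 17 gene lists with at least 5 measured members in the 5 comparisons, with a bar from the first to the third quartile of the members, filled where the camera adjusted p was under 0.05 (each panel has its own axis). In the comparison of Anillin 4N with control 4N, G2/M genes have the lowest median (-2.12) and p53 targets the highest (0.62).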

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

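The tests of a mixed 4N gate, of genome doubling, of the share of G2/M cells, of fewer cycling cells and of lost short transcripts were chosen only after the results they bear on had been seen. The test of sequencing depth was added after the data had been seen and before its own result was, and other splits of the libraries were planned. The siRNA effect differed between the gates, by the interaction test, for 9 lists and for 69 of 152 named genes, 26 with a positive and 43 with a negative value. Named genes were picked for large changes, and over all 12892 genes tested it was past the threshold for 2019 (15.7%). Of the 9 lists 1, p53 targets, was called with an estimated correlation.

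For p53 targets the median interaction was 0.37, with MDM2 at 1.07, BTG2 at 0.87 and CDKN1A at 0.79. A 4N gate that only mixed 2N-like cells with G2/M cells would lie between the 2N cells and control 4N cells, but 28 of 38 members were higher in Anillin 4N than in both Anillin 2N and control 4N, against 0.915% of all genes tested. The median between the Anillin fractions was 0.4103 with all reads and 0.4124 with every library thinned to 17412742 reads. Thinning keeps the expected RPKM of a gene, so this median could hardly move and does not decide on unequal depth. A candidate explanation that stays open is genome doubling adding to the effect of the siRNA, which needs a positive interaction that holds with an estimated correlation (adjusted p = 0.0257). The same values would be there if p53 targets rose in G2/M cells after the siRNA without any doubling, which the sort by DNA content does not separate.

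For G2/M genes the median interaction was -1.28 (adjusted p = 0.139 with an estimated correlation), with ANLN itself at -1.96, KPNA2 at -1.94, CDK1 at -1.85, CDCA8 at -1.84, FAM83D at -1.81, PIF1 at -1.76, CCNB1 at -1.18 and MKI67 at -0.83. With thinned libraries the median was -1.282, beside -1.284 with all reads. As above, this does not decide on unequal depth. Whether one smaller share of G2/M cells in the 4N gate is the whole cause is not decided. The measure, the share of the control difference kept on RPKM, where cells add, can also move with siRNA effects in 2N cells (3682 genes). Of 1703 genes lower in control 4N than in control 2N cells, the 193 with a log2 fall of at least 0.5 kept a median share of 0.279 (95% bootstrap interval over genes 0.23 to 0.334). G2/M genes kept 0.12 (0.114 to 0.128). Without each library in turn these shares were 0.237 to 0.304 and 0.115 to 0.126. The bootstrap treats genes as independent, which they are not. On the log2 scale, where cells do not add, the order was reversed, at 0.255 (0.204 to 0.297) and 0.337 (0.293 to 0.399). A smaller share, with or without a change within the cells, stays open. Fewer cycling cells in the Anillin siRNA cultures may account for part of it, since 32 of 32 G1/S genes fell among 2N cells with a median of -0.69.

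The 6 largest falls in control 4N against control 2N were of short unnamed features. There the median was -0.11 for 206 snoRNA genes (95% bootstrap interval over genes -0.15 to -0.04), -0.21 for 62 snRNA genes (-0.38 to -0.06) and -0.11 for 95 genes of miscellaneous RNA (-0.22 to 0.02), with 12, 5 and 7 genes past the threshold as lower. In Anillin 4N against control 4N the medians were 0.05 (-0.04 to 0.17), 0.20 (0.05 to 0.39) and 0.14 (-0.05 to 0.21), and that of snoRNA genes was also below 0 in Anillin 2N against control 2N (-0.08, -0.15 to -0.04). A loss of short RNA while the control 4N libraries were made could give the first values but needs higher values in Anillin 4N, which intervals that include 0 do not show for snoRNA and miscellaneous RNA, so it stays open beside a lower level in the cells. The largest rise of an unnamed short feature in Anillin 4N against control 4N (2.13) and the largest fall in control 4N against control 2N (-2.52) were of the same feature (ENSG00000265150), at 34.9 ± 35.5 RPKM in control 2N, 4.21 ± 2.00 in control 4N, 37.9 ± 18.3 in Anillin 2N and 19.7 ± 6.85 in Anillin 4N, and the fall was not called without control 4N replicate 2 (adjusted p = 0.0521), nor the rise without control 4N replicate 2 or 3 or Anillin 4N replicate 1 or 3 (0.0512 to 0.0801).

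Calls of the other lists with an interaction were lost with an estimated correlation (adjusted p = 0.139 to 0.586), and those of G1/S, YAP and inflammatory genes also with fry (0.0593, 0.2 and 0.0603). They had medians of -0.40 (G1/S), -0.34 (centrosome and centriole), -0.20 (cytokinesis and septins), -0.16 (heat shock), -0.14 (G1 cyclins and CDK inhibitors), 0.17 (inflammatory genes) and 0.094 (YAP/TAZ-TEAD targets). Without single libraries named above, the YAP list (adjusted p = 0.0698) and the heat shock list (0.0558 to 0.111) were not called. Negative interactions among their genes were those of KIF23 (-1.56), CDKN2D (-1.45), RACGAP1 (-1.37), CDKN2C (-1.10), ORC6 (-1.07), PLK4 (-1.06), CNTROB (-0.95), CDKN3 (-0.88), CDK2 (-0.85), HSPA8 (-0.63), HSP90AA1 (-0.43), HSPH1 (-0.30), DNAJA1 (-0.27) and RB1 (-0.22). Positive were IL1B (0.62), PTGS2 (0.59), ARHGEF17 (0.24) and an unnamed pseudogene (1.05, at 22.2 RPKM in Anillin 2N and 52.4 in Anillin 4N). CCNE2 (0.40) was not called with voom (adjusted p = 0.434), and an unnamed snoRNA (1.13) failed the filter on reads.

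The other genes named for the interaction lost their call without single libraries. FEN1 (-0.77) did so without control 4N replicate 1 or 3 or any replicate of Anillin 2N or Anillin 4N (adjusted p = 0.0553 to 0.102). DNAJB1 (-0.42) did so without control 2N replicate 1 or 2, any replicate of control 4N, Anillin 2N replicate 1 or 2, or Anillin 4N replicate 2 or 3 (0.0680 to 0.0909). ANKRD1 (0.56) lost it without control 2N replicate 2 or 3, control 4N replicate 1 or 3, Anillin 2N replicate 1, or Anillin 4N replicate 2 or 3 (0.0563 to 0.0771), and CEP250 (0.23) without control 2N replicate 1 or 3, control 4N replicate 1 or 2, Anillin 2N replicate 1 or 2, or any replicate of Anillin 4N (0.0728 to 0.0931). For RRAD (1.13) any library but control 2N replicate 2 or Anillin 2N replicate 3 ended the call (0.0624 to 0.103), for the pseudogene RPS27P2 (1.09) any but control 2N replicate 3 (0.0511 to 0.104), and for an unnamed feature of 137 bases (1.31) any but control 2N replicate 3, control 4N replicate 3 or Anillin 2N replicate 1 (0.0774 to 0.0985). Without a filter all 7 of these calls were lost (0.0725 to 0.117).

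Of the 10 splits of the 6 libraries in each comparison of a pair of groups, 1, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real and the highest other count were 6638 and 0 for Anillin 4N against control 4N, 461 and 1 for Anillin 4N against Anillin 2N, 4782 and 0 for control 4N against control 2N, and 3682 and 1 for Anillin 2N against control 2N. Each other split mixes the groups, so the difference between them widens the spread and lowers the count, and these low counts do not measure chance. For the interaction, 9 of 100 drawn splits (of 200 that exchange siRNA labels within the gates) gave at least the real 2019 genes, so chance is not excluded by this count. The highest other value, 6892, came from exchanging all siRNA labels in 1 gate, which turns the interaction into the sum of both siRNA effects, and points to the structure of the samples. Of the 8 other splits as large, 7 exchanged 2 or 3 more libraries per siRNA in one gate than in the other, and the median of the other splits was 0 genes.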

How the results depend on the processing

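Settings on recovered reads (voom and log2 RPM) were chosen only after the data had been seen, as was leaving out libraries for the correlations. The count tools listed beforehand were not run, since the values are RPKM, and voom took their place. No paired analysis was possible because the labels give sample numbers that tie no 2N fraction to a 4N fraction, and replicates were numbered in order of deposit. A fit of only the 2 groups compared does not exist for the interaction. ANLN fell under every setting and without each library, between -6.61 and -3.04 among 4N cells (highest adjusted p = 5.63e-06) and between -4.67 and -1.29 among 2N cells (0.0035).

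Of 257 results of named genes past the threshold, 200 stayed past it under every setting with all libraries and 207 without each library in turn. Their log2 changes were over 1.5 times larger for 31 with voom, 25 with log2 RPM and 22 with a pseudocount of 0.1, and smaller by as much for 1, 6 and 0. They were smaller by as much for 9 with a pseudocount of 1 and for 8 with quantile scaling, which made 4 larger. Of 55 called list medians none turned in sign. Over 1.5 times larger were 16 with voom, 6 with a pseudocount of 0.1 and 6 with quantile scaling, and smaller by as much were 10 with quantile scaling and 2 with a pseudocount of 1. Counts of changed genes of any size stayed within 1.5 times under either scaling, filter and pseudocount. They rose to 10442 (log2 RPM) for Anillin 4N against control 4N, to 1191 (library quality weights), 905 (voom) and 1068 (log2 RPM) for Anillin 4N against Anillin 2N, to 8138 (voom) and 7896 (log2 RPM) for control 4N against control 2N, to 6402 (voom) and 5695 (log2 RPM) for Anillin 2N against control 2N, and to 3260 (voom) and 3499 (log2 RPM) for the interaction. Voom and log2 RPM test more genes, and whether this is the cause was not tested. With only the 2 groups fitted, Anillin 2N against control 2N gave 2347 genes, with fewer samples behind the spread. Counts of genes changed at least 2-fold depend on the pseudocount, which compresses low values. In the order of the comparisons they were 417, 29, 252, 67 and 157, and 1516, 155, 745, 523 and 353 with voom. Those of the 4 comparisons of a pair of groups were 888, 99, 428 and 241 with log2 RPM and 271, 13, 166 and 30 with a pseudocount of 1. With a pseudocount of 0.1 the siRNA gave 699 genes among 4N and 172 among 2N cells, and the Anillin fractions differed in 69. Among 2N cells the siRNA gave 114 with library quality weights and 102 without control 2N replicate 2. Without 1 library the counts of any size were 5727 to 6369, 241 to 316, 3381 to 4645, 2668 to 3857 and 1295 to 2027. Those of Anillin 4N against Anillin 2N moved by over 1.5 times without replicate 2 or 3 of either group (241, 300, 243 and 306), and that of the interaction without control 4N replicate 1 (1295).

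The correlation of the siRNA effects in the gates was 0.549 with a pseudocount of 0.1, 0.571 without a filter, 0.745 at a mean RPKM of at least 1 and 0.758 with log2 RPM. That of the differences between 4N and 2N cells was 0.302, 0.316, 0.508 and 0.533 under the same settings, and 0.331 to 0.393 without 1 library, lowest without Anillin 4N replicate 3. The cause was not tested. With an estimated correlation 1, 1, 0, 2 and 1 lists were called in place of 11, 9, 14, 12 and 9, which comes from that setting's wider spread. The ATF4 list in controls, with a median of 0.0020, was called higher by fry (adjusted p = 0.0117) and was lower by camera, which compares it with other genes.

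Changes not past the threshold that turned in sign were those of CCND1 in Anillin 4N against control 4N (-0.065 to 0.072 without 1 library, negative without control 4N replicate 2 or Anillin 4N replicate 3), GAPDH in Anillin 4N against Anillin 2N (-0.043 to 0.12, negative without Anillin 2N replicate 3), CCN1 (-0.072 to 0.13) and CCN2 (-0.077 to 0.24) in Anillin 2N against control 2N (negative without control 2N replicate 3). With quantile scaling CCND1 and MDM2 in controls were at -0.0051 and -0.017, and the interaction of GAPDH at 0.069. The cause was not tested. Thinned to 17412742 reads per library, the counts of changed genes were 6070, 361, 4248, 3132 and 1627, below those with all reads in each comparison, so depth limits how many genes are called.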

Other observations

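The lists of complement genes, lysosomal genes and cytosolic ribosomal proteins were chosen only after the data had been seen, and their p-values are adjusted over these 3 lists. Of 10 measured complement components and regulators, 6 rose among 4N cells after Anillin siRNA and 2 fell (6 and 2 when adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00747, and adjusted p = 0.365 with an estimated correlation). C4A rose by 1.26 ± 0.08 (adjusted p = 1.10e-06), C4B by 1.20 ± 0.10, C3, the central component of the cascade, by 0.57 ± 0.08, C1R by 0.46, C1S by 0.39 and CLU by 0.28. CD59 (-0.30 ± 0.03) and CD55 (-0.16 ± 0.04), which protect cells from complement, fell. Among 2N cells the median was 0.37 (camera adjusted p = 0.00185, and adjusted p = 0.3 with an estimated correlation), with C4B at 1.13 ± 0.10, C4A at 1.09 ± 0.08 and C3 at 0.80 ± 0.08 higher and CD55 (-0.29) and CD59 (-0.23) lower. The list was lower in 4N than in 2N cells in Anillin cultures (median -0.14, camera adjusted p = 0.00495, and adjusted p = 0.587 with an estimated correlation) and in controls (median -0.20, camera adjusted p = 0.00779, and adjusted p = 0.396 with an estimated correlation), and the interaction had camera adjusted p = 0.401. With voom on recovered reads, which measures 17 of these genes, the median was 0.586 among 4N cells after Anillin siRNA and -0.388 in control 4N against control 2N cells.

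Of 41 measured lysosomal genes, 24 rose among 4N cells after Anillin siRNA (24 when adjusted over the list alone), with a median of 0.20 (camera adjusted p = 3.09e-06, and adjusted p = 0.337 with an estimated correlation). The sulfatase SGSH rose by 0.79 ± 0.06, prosaposin (PSAP) by 0.75 ± 0.08, the peptidase TPP1 by 0.71 ± 0.09, acid alpha-glucosidase (GAA) by 0.66 ± 0.07 and CTSA by 0.64 ± 0.05. The cathepsins CTSL (-0.38 ± 0.04) and CTSB (-0.18), and GLA (-0.36 ± 0.07), were among those that fell. Among 2N cells 20 rose (24 when adjusted over the list alone), with SGSH at 0.62 ± 0.06 and PSAP at 0.60 ± 0.08 (median 0.15, camera adjusted p = 9.80e-07, and adjusted p = 0.298 with an estimated correlation). In controls the list was lower in 4N than in 2N cells (median -0.08, camera adjusted p = 0.00296, and adjusted p = 0.396 with an estimated correlation). Between the Anillin fractions it had camera adjusted p = 0.374, and in the interaction a median of 0.07 (camera adjusted p = 0.0083, and adjusted p = 0.792 with an estimated correlation).

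The 76 cytosolic ribosomal proteins had medians between -0.07 and 0.08 in the 5 comparisons. They were higher as a list in Anillin 2N against control 2N (0.07, camera adjusted p = 1.99e-05, and adjusted p = 0.451 with an estimated correlation) and in control 4N against control 2N (0.08, camera adjusted p = 0.0124, and adjusted p = 0.661 with an estimated correlation). The other comparisons had camera adjusted p = 0.126 (Anillin 4N against control 4N), 0.374 (Anillin 4N against Anillin 2N) and 0.202 (interaction, median -0.067). With voom on recovered reads the interaction was called lower (median -0.066, 69 of 76 lower, camera adjusted p = 0.0178, and adjusted p = 0.791 with an estimated correlation).

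CCND2, CCNE1 and LATS2 did not pass the filter on RPKM and were tested on recovered reads with limma-voom. CCND2, with 10 to 55 reads per library, rose after Anillin siRNA by 1.29 among 4N cells (adjusted p = 0.00244) and by 1.24 among 2N cells (adjusted p = 0.000741). CCNE1, cyclin E1, was lower in 4N than in 2N cells in controls (-1.06, adjusted p = 9.06e-07) and after Anillin siRNA (-0.67, adjusted p = 0.00381), and its interaction of 0.39 had adjusted p = 0.161. LATS2, a kinase of the Hippo pathway, rose after Anillin siRNA by 0.42 among 4N cells (adjusted p = 0.000135) and by 0.22 among 2N cells (adjusted p = 0.0238), with an interaction of 0.20 (adjusted p = 0.216).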
